A study of Mus musculus with 19 samples.

How the data were processed

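Forebrain RNA from 19 samples was extracted with a lipid tissue kit, labelled with biotin and hybridised to Affymetrix Mouse Gene 2.0 ST arrays, per the labels' protocols. The deposited values are log2 expression of one value per probe set and array, on a scale that ran from 2.18 to 14.2. The tools named in the submitters' processing notes are RMA (background correction, quantile normalization and summary of probes), oligo and limma, with no versions given. Their roles and order, and the genome build, are not given in the sources used here. Correlations between arrays over all probe sets ran from 0.981 to 0.993, and no columns were identical. Of the 8751 rows, 346 repeated the values of an earlier row. No column belonged to another series. Arrays give no read depth, and their number limits the precision.

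Samples were grouped by genotype and treatment from their labels. Genes were named from the platform annotation only where a probe set had 1 symbol, and 1045 of 1121 such genes were found by identifier in the mouse gene table of assembly GRCm38.p6. That table was used only for gene classes and for which genes neighbour Epha4. For a gene with several probe sets, the one with the highest mean was used.

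Each row was tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values. The 4 group means were fitted on all 19 arrays without covariates, and moderated tests were adjusted by the Benjamini-Hochberg method over 8751 rows with a threshold of 0.05. The 7 comparisons were sleep deprivation in wild type, in the knockout and averaged over genotypes, knockout against wild type in controls, after sleep deprivation and averaged over conditions, and the interaction. Gene lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 17 lists tested. The 29 tissue and treatment lists were fixed before the data were examined. Because only 1 of them had 3 measured genes, 16 lists were added, 15 of them chosen from the gene names before any value was tested and 1 holding the genes near Epha4.

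The rule for named genes was Epha4, the 12 highest and 12 lowest called genes of the sleep deprivation and genotype effects averaged over the other factor and 5 of each for the interaction, with predicted, unnamed-clone, microRNA and small nucleolar genes passed over. Where fewer than 5 genes passed, the 5 smallest p were given, and up to 4 genes with the smallest p were given per list. Of 12 sleep-responsive genes named in advance, only Fkbp5 was measured under its own symbol. The genes called in the genotype comparison after sleep deprivation were named after their values were seen.

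Scripts were tested on simulated data with the real group sizes. In each set, 100 probe sets had each size of change, and noise was drawn independently for each value. For the interaction, 45% of probe sets with a log2 change of 0.5 and 89% of those with a change of 1 were recovered, and for the sleep deprivation effect averaged over genotypes 89% and 100%. In the 1 simulated set per comparison, 2.9% to 8.3% of the calls were false, with 8.2% for the interaction and 8.3% for genotype after sleep deprivation, above the nominal 5%. Of 20 simulated lists without a shift, 2 had a camera p under the threshold. Alternatives covered the prior variance, array weights, filters on dim and multiply annotated rows, averaging of rows, quantile normalization, median centring, the arrays in the fit, the replicate number as a block, the threshold and leaving out each array. Region marker scores as covariates were not run, since no list of region markers had more than 1 measured gene. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.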

Results

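Transcript levels were measured in the forebrain of mice that lack the receptor tyrosine kinase EphA4 and in wild-type littermates, all of a mixed strain background and kept under 12 h of light and 12 h of dark. Mice were left undisturbed or kept awake for 6 h. The arrays fell into 4 groups: 4 wild-type controls, 6 sleep-deprived wild-type mice, 4 knockout controls and 5 sleep-deprived knockout mice. Each of the 19 arrays was labelled as a separate sample. Nothing in the labels states that each came from its own animal, so p-values measure the spread between these samples. The values were log2 expression on 8751 probe sets, with array medians from 5.90 to 6.07, and the number of arrays limits the precision. The series' description warns that its tables are incomplete. Of the probe sets, 1308 carried 1 gene symbol and stood for 1121 genes, 1178 carried several symbols and 6265 were unnamed here. No probe set was named Epha4, so its level could not be used to check the genotype labels.

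Few of the genes chosen in advance for this tissue and treatment were present in these values. Measured here means present under a symbol of its own among the 8751 probe sets. Since the series is described as incomplete, absence does not show that the array lacks a gene. The adjustment of p-values and the alternatives with quantile normalization or median centring used these probe sets alone. Of 593 genes in 29 lists, 14 were present under a symbol of their own. For 18 lists no gene was measured, for 10 lists 1 or 2 genes were measured, and 1 list had 3. The lists of immediate early genes, clock genes, Eph receptors and astrocyte, oligodendrocyte and microglia markers were among those with no gene, and no statement on these groups is made. The 3 measured glutamate genes, Grin2c and Grin2d (NMDA receptor subunits) and Shank3 (a postsynaptic scaffold), did not pass the test for the sleep deprivation effect averaged over genotypes, over all probe sets or adjusted over the list alone (0 of 3 genes). As a list their mean log2 change was 0.05, with an adjusted p = 0.73 in the competitive list test and an adjusted p = 0.81 with an estimated correlation. None of the 3 passed over all probe sets in any of the 7 comparisons. Adjusted over the list alone, 1 gene was higher for sleep deprivation in the knockout, for genotype after sleep deprivation and for the interaction. Grin2c had the smallest p in each of these, with log2 changes of 0.28, 0.23 and 0.39.

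The effect of sleep deprivation averaged over both genotypes asked which transcripts changed after 6 h of enforced wakefulness. Fkbp5, a co-chaperone of the glucocorticoid receptor and a glucocorticoid-induced gene, rose 1.34-fold (log2 change 0.42 ± 0.07, SE; adjusted p = 0.0065). Its mean log2 level went from 7.64 ± 0.13 (SD, n = 4) to 7.99 ± 0.13 (SD, n = 6) in wild type and from 7.70 ± 0.08 (SD, n = 4) to 8.19 ± 0.19 (SD, n = 5) in the knockout. Pdzd2, which encodes a protein with several PDZ domains, rose 1.18-fold (log2 change 0.24 ± 0.05, SE; adjusted p = 0.027). Mir219a-2, a precursor of the microRNA miR-219, which is abundant in oligodendrocytes, fell by 0.36 on the log2 scale (SE 0.06, adjusted p = 0.013). These were the 3 genes past the threshold among 23 probe sets in limma's test, 18 higher and 5 lower. Some of the 23 repeated the values of another, leaving 19 distinct profiles. With identical rows counted once, an alternative chosen after seeing the data, 16 passed, 11 higher and 5 lower. The next smallest p were those of Gm20385 (log2 change 0.24, adjusted p = 0.051) and Wdr78 (0.26, adjusted p = 0.060), and both passed with only the probe sets of 1 symbol tested (adjusted p = 0.022 and 0.023). Of the other probe sets, 11 carried several symbols and 9 were unnamed. The largest change among the 23 was that of an unnamed one, 17529227 (log2 change 0.70, adjusted p = 0.047). It changed by -0.33 in wild type and 1.73 in the knockout, and its averaged call was lost in 23 of 30 alternatives. With each array centred on its median the split was 9 higher and 5 lower, with quantile normalization 13 and 7, and without WT_control replicate 1 the count was 14. Pdzd2 missed the threshold after median centring (adjusted p = 0.21) and on leaving out any of 10 arrays, each of the WT_control arrays, KO_control replicates 1 and 3 and KO_sleep_deprived replicates 1 to 4, with adjusted p from 0.051 to 0.084. Fkbp5 and Mir219a-2 passed on leaving out each of the 19 arrays in turn, and Mir219a-2 missed the threshold without the 3 arrays of lowest weight (adjusted p = 0.059), an alternative chosen after seeing the data. Over all alternatives run, Pdzd2 missed it in 12 of 32, Mir219a-2 in 2 of 32 and Fkbp5 in 1 of 32.

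Among other genes with roles in stress responses, Hspa8, the constitutive cytosolic chaperone, had a log2 change of 0.20 ± 0.05 (SE, adjusted p = 0.15) and Elk1, a transcription factor activated by MAP kinases, 0.16 ± 0.05 (SE, adjusted p = 0.29). Of 22 stress-responsive and chaperone genes, Fkbp5 was the 1 member that passed over all probe sets, 3 were higher when adjusted over the list alone, and 17 had a positive sign. The mean log2 change of this list was 0.05, with an adjusted p = 0.42 in the competitive test and an adjusted p = 0.81 with an estimated correlation. Gpd1, a glycerol-3-phosphate dehydrogenase that responds to glucocorticoids, had a log2 change of 0.19 ± 0.05 (SE, adjusted p = 0.20). Among 9 histone genes, H4c9 had a log2 change of 0.48 ± 0.11 (SE, adjusted p = 0.092) and H4c14 0.27 ± 0.07 (SE, adjusted p = 0.12), and no histone gene passed over all probe sets, while 2 were higher when adjusted over the list alone. Of the 9, 5 had a positive and 4 a negative sign, with a median log2 change of 0.04. The mean log2 change of the histone list was 0.12, with an adjusted p = 0.42 in the competitive test and an adjusted p = 0.81 with an estimated correlation. It had an adjusted p = 0.088 with fry, which asks whether a list moves one way and does not compare it with other genes. The list of 43 microRNA precursors held 1 gene that fell, Mir219a-2, and its test gave an adjusted p = 0.85.

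Within wild type, sleep deprivation gave 0 probe sets past the threshold in limma's test, with 683 at an unadjusted p under 0.05. The 5 genes with the smallest p were Pdzd2 (log2 change 0.31), Mir376a (-0.50), Mir219a-2 (-0.36), Gm12592 (-0.31) and Gpd1 (0.27), with adjusted p from 0.23 to 0.30. Fkbp5 had a log2 change of 0.34 ± 0.09 (SE, adjusted p = 0.30). In simulated data of this size, 75% of probe sets with a log2 change of 0.5 and 98% of those with a change of 1 were recovered for this comparison. That simulation changed 100 probe sets of each size and drew noise independently. Recovery with fewer changes or with noise shared between probe sets may be lower. On leaving out single arrays the count was 3 without WT_sleep_deprived replicate 5 and 1 without WT_sleep_deprived replicate 3 or 6.

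Within the knockout, 23 probe sets passed the threshold after sleep deprivation, 22 higher and 1 lower. The 4 named genes were Gm6625 (1.70-fold, log2 change 0.77 ± 0.12, SE; adjusted p = 0.011), Gm20385 (log2 change 0.45 ± 0.07, SE; adjusted p = 0.011), Fkbp5 (1.41-fold, log2 change 0.49 ± 0.10, SE; adjusted p = 0.044) and Gm6272 (log2 change 0.38 ± 0.08, SE; adjusted p = 0.0495). Gm3286 was next, with a log2 change of -0.40 and an adjusted p = 0.053. Fkbp5 missed the threshold in 11 of the 19 fits without 1 array (adjusted p from 0.051 to 0.12) and Gm6272 in 17, while Gm6625 and Gm20385 passed in all 19. Over all 33 alternatives Fkbp5 missed it in 16, Gm6272 in 23 and Gm6625 and Gm20385 in 1 each. Tests of the added gene lists within one genotype were chosen after seeing the data and adjusted only within a comparison. With fry, 3 lists passed in this comparison and none in the other 6: 9 histone genes (mean log2 change 0.21, adjusted p = 0.036), 23 genes of mitochondrial proteins (0.09, adjusted p = 0.044) and the 22 stress-responsive and chaperone genes (0.08, adjusted p = 0.044). None passed the competitive test (adjusted p = 0.15, 0.19 and 0.19) or that test with an estimated correlation (0.61, 0.68 and 0.68). Adjusted over the list alone, 4 histone, 0 mitochondrial and 2 stress genes were higher. Of the 9 histone genes, 6 had a positive and 3 a negative sign. Fry also has a mixed test, which asks for changes of either sign, and in it lists passed in other comparisons too. Among these were the stress list for sleep deprivation averaged over genotypes (adjusted p = 4.5e-07) and pseudogenes for genotype after sleep deprivation (adjusted p = 0.00030). In that stress list Fkbp5 was the 1 member past the threshold over all probe sets. Fry's test for a move in one direction gave it an adjusted p = 0.088. The mixed test can pass on few strong members, so it does not show that the list moved as a whole. With quantile normalization 24 passed, 18 higher and 6 lower. Of the 23, 8 had the same sign of change in wild type. Across all probe sets, which are not independent replicates, the responses of the 2 genotypes had a Pearson correlation of -0.19 (jackknife SE 0.11), and -0.08 over the 1121 genes with 1 symbol. Of the 100 probe sets with the smallest p in wild type, 60 had the same sign in the knockout, and of the 100 with the smallest p in the knockout, 42 had the same sign in wild type. The count fell to 10 without WT_control replicate 1, WT_sleep_deprived replicate 6 or KO_control replicate 1, to 14 without WT_control replicate 2 or WT_sleep_deprived replicate 5, to 13 without WT_control replicate 3 and to 11 without WT_control replicate 4 or KO_control replicate 2. It was 15 without KO_control replicate 4 and 9, 8, 6 and 12 without KO_sleep_deprived replicates 1, 2, 3 and 5.

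**Figure D1:**
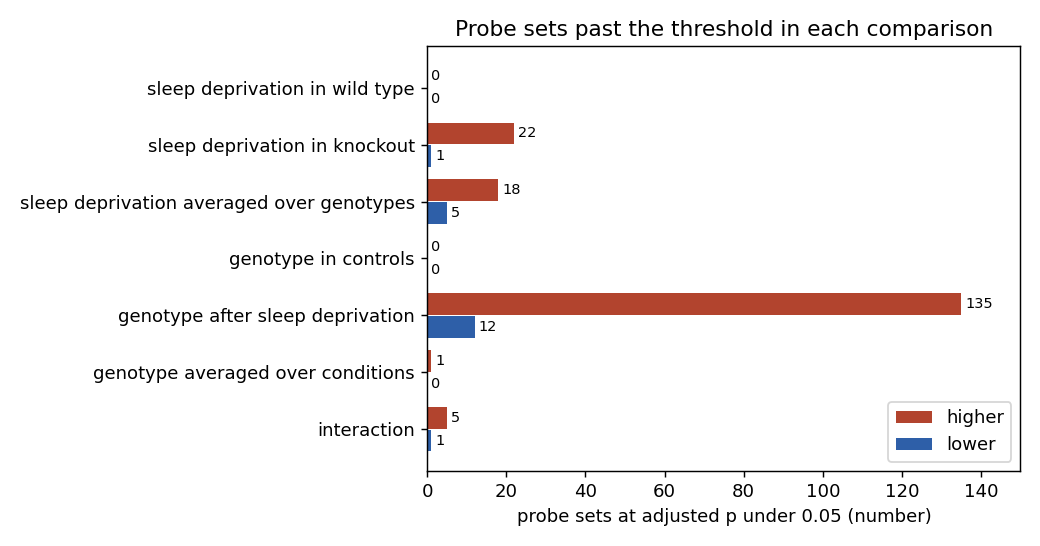
Number of probe sets at adjusted p under 0.05 (horizontal axis) in each of the 7 comparisons, with red bars for higher and blue bars for lower values. The genotype comparison after sleep deprivation had 135 higher and 12 lower, and the comparisons in wild type and in controls had none.

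In control mice, knockout and wild type did not differ for any probe set past the threshold in limma's test, with 476 at an unadjusted p under 0.05 and a smallest adjusted p of 0.79. The 5 genes with the smallest p were Mir376a (log2 change -0.50), Gm15114 (-0.45), Gm21136 (0.37), Kif5b (-0.26), which encodes a kinesin heavy chain, and Gm4701 (0.26). Simulated changes of 0.5 and 1 on the log2 scale were recovered at 65% and 93% for this comparison, under the same simulation settings and limits.

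After sleep deprivation, 147 probe sets differed between knockout and wild type, 135 higher and 12 lower in the knockout. Most, 125, were unnamed, 4 carried several symbols and 18 stood for 13 genes, which were named after their values were seen. Vmn1r148, a vomeronasal receptor gene, was 2.15-fold higher in the knockout (log2 change 1.10 ± 0.16, SE; adjusted p = 0.0018), at 6.84 ± 0.35 (SD, n = 5) against 5.74 ± 0.24 (SD, n = 6). Gm6625 was 1.60-fold higher (log2 change 0.67 ± 0.11, SE; adjusted p = 0.0079). Pcid2, which takes part in messenger RNA export, was 1.30-fold higher (log2 change 0.38 ± 0.07, SE; adjusted p = 0.010). Ndufa11, an accessory subunit of mitochondrial complex I, was lower by a log2 change of -0.47 ± 0.10 (SE, adjusted p = 0.026), at 6.95 ± 0.25 (SD, n = 5) against 7.42 ± 0.11 (SD, n = 6). Ssxb8 (0.66), Gm5528 (0.57), Gm906 (0.48), Gm19399 (0.44), Gm13981 (0.33), Gm6272 (0.30), Gm8618 (0.29) and Mir466b-2 (0.51, on 6 probe sets with identical values) had positive log2 changes past the threshold. Polr2k, a subunit shared by the RNA polymerases, had a log2 change of 0.55 (adjusted p = 0.045) on 1 of its probe sets and 0.11 (adjusted p = 0.58) on its brighter one.

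The size of this difference depended on which arrays entered. The split was 96 higher and 37 lower with quantile normalization and 83 and 26 with median centring. Fitted on the sleep-deprived arrays alone, 36 probe sets passed. The count was 89, 78, 298 and 78 without WT_sleep_deprived replicates 1, 2, 3 and 4, and 67 and 94 without KO_sleep_deprived replicates 1 and 3. Vmn1r148 and Gm6625 passed in all 33 alternatives run for them. Pcid2 and Ndufa11 missed the threshold when the fit held only the sleep-deprived arrays (adjusted p = 0.054 and 0.074) and without the 3 arrays of lowest weight (adjusted p = 0.055 and 0.060), and Ndufa11 also without WT_sleep_deprived replicate 2 or 4 or KO_sleep_deprived replicate 1 or 3 (adjusted p from 0.055 to 0.068). On leaving out each of the 19 arrays, Gm8618 missed it in 15 fits, Gm19399 in 13, Mir466b-2 in 12, Gm6272 in 11, Gm906 in 9, Ssxb8 in 5, Gm5528 in 4 and Gm13981 in 1. Over all 33 alternatives these counts were 22, 23, 19, 16, 14, 8, 7 and 3, in the same order.

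Averaged over both conditions, 1 unnamed probe set, 17529227, was higher in the knockout, by a log2 change of 0.99 ± 0.15 (SE, adjusted p = 0.013). The difference lay in the sleep-deprived mice, with a log2 change of 2.02 (adjusted p = 1.3e-05), against -0.04 in controls (adjusted p = 0.98). The averaged call was lost without WT_control replicate 3 (adjusted p = 0.057), when 0 probe sets passed, and without the 3 arrays of lowest weight (adjusted p = 0.098). Without KO_control replicates 2 and 4, 3 and 2 probe sets passed. No named gene passed over all probe sets, and with only the probe sets of 1 symbol tested, Vmn1r148 did (adjusted p = 0.040). The 5 genes with the smallest p were Vmn1r148 (log2 change 0.64), Gm4701 (0.23), H4c14 (-0.26), H2-Q10 (0.46), a class I histocompatibility gene, and Mir219a-2 (-0.23), with adjusted p from 0.11 to 0.28. The mean log2 change over 23 ribosomal protein genes was -0.04, with 16 members of negative and 7 of positive sign and none past the threshold over all probe sets or adjusted over the list alone. The list test gave an adjusted p = 0.015 at the preset correlation and an adjusted p = 0.77 with an estimated correlation. The correlation estimated between members was 0.17, far above the preset 0.01, so the smaller p understates their dependence. Rpl30 (log2 change -0.15), Rps13 (0.23), Rpl32 (-0.12) and Rpl34 (-0.12) had the smallest p. The call at the preset correlation was also lost after quantile normalization (adjusted p = 0.090) and without WT_control replicate 2, WT_sleep_deprived replicate 3, KO_control replicate 2 or 3, or KO_sleep_deprived replicate 5. Around the Epha4 gene, 0 measured genes lay within 5 Mb, 7 within 10 Mb and 14 within 20 Mb, and 0 of these passed in this comparison. After sleep deprivation 1 of them, Gm5528, passed, which is 1 of 7 against 11 of 1114 elsewhere for 10 Mb (Fisher's exact test, two-sided, p = 0.073) and 1 of 14 against 11 of 1107 for 20 Mb (p = 0.14).

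The interaction asked whether the response to sleep deprivation differed between the genotypes. It called 6 probe sets, all unnamed, 5 with a higher change in the knockout and 1 with a lower one. Probe set 17529227 rose by 1.73 ± 0.21 (log2, SE) in the knockout and changed by -0.33 ± 0.20 (SE) in wild type, a difference of 2.06 ± 0.29 (SE, adjusted p = 0.0055). It read 6.81 ± 0.41 (SD, n = 5) on the sleep-deprived knockout arrays and no more than 5.37 on any other array. The means of the other 3 groups, 4.79 to 5.12, lay below the array medians, and the probe set was among the dimmest 40% of rows, so the filter on those left it out. Probe set 17366928 differed by 0.73 ± 0.11 (SE, adjusted p = 0.0055) and missed the threshold after quantile normalization (adjusted p = 0.072) and without the 3 arrays of lowest weight (adjusted p = 0.054), 2 of 31 alternatives. Probe set 17267654 differed by -0.76 ± 0.13 (SE, adjusted p = 0.023) and missed it in 9 of 31, of which 7 were among the 19 fits without 1 array. These were singled out after their values were seen. Among named genes none passed, and Gm6625 (0.80), Mir376a (0.69), Pcid2 (0.44), Gm20385 (0.41) and Vmn1r148 (0.93) had the smallest p, with adjusted p from 0.17 to 0.20. The mean interaction over 14 small nucleolar RNAs was 0.21 on the log2 scale, with 12 of positive sign. The list test gave an adjusted p = 0.034 at the preset correlation and an adjusted p = 0.66 with an estimated correlation. The correlation estimated between members was 0.25, far above the preset 0.01, so the smaller p understates their dependence. Snord19 (0.77), DQ267101 (0.27), Snord22 (0.25) and AF357425 (0.17) had the smallest p. None passed over all probe sets, and 1 did when adjusted over the list alone. The call at the preset correlation was also lost after quantile normalization (adjusted p = 0.23) and in 8 of the 19 fits without 1 array. The interaction count was 2 without WT_control replicate 1, KO_control replicate 2 or 4 or KO_sleep_deprived replicate 1 or 3, 3 without WT_control replicate 2 or 3, and 41 without WT_sleep_deprived replicate 3.

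**Figure D2:**
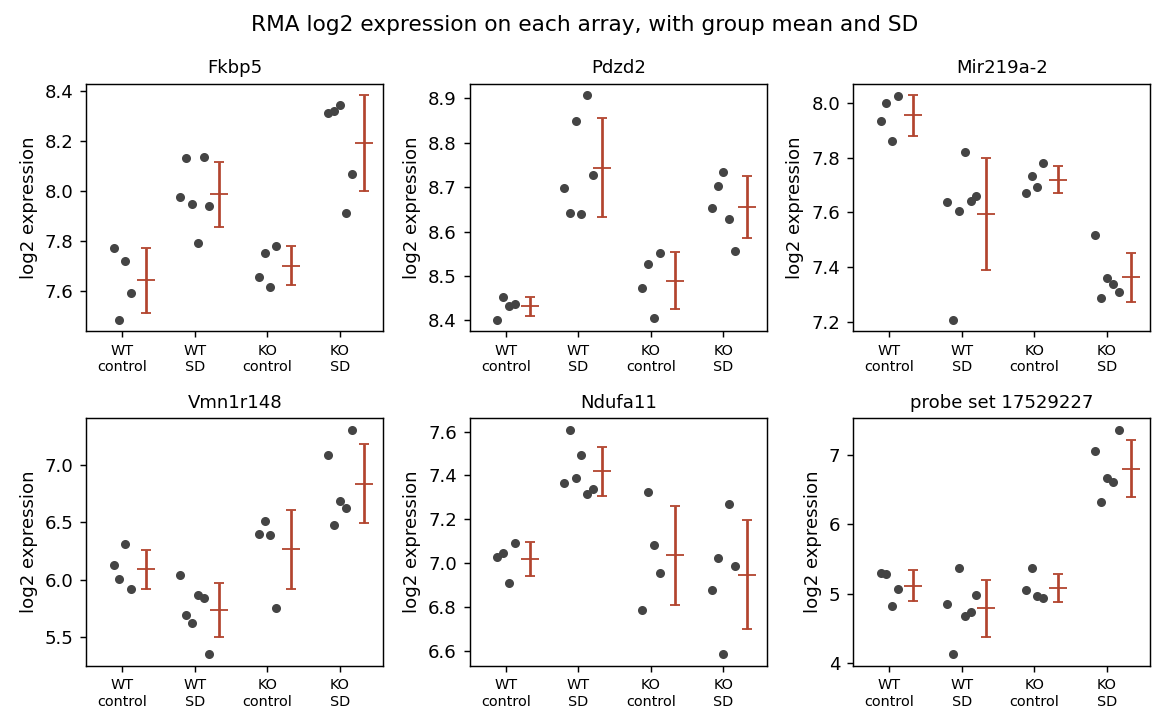
RMA log2 expression (vertical axes) on each array of the 4 groups for 5 genes and 1 unnamed probe set, where SD on the horizontal axes stands for sleep-deprived. Dots are arrays, and red marks are the group mean with its standard deviation. Probe set 17529227 read at least 6.32 on the 5 sleep-deprived knockout arrays.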

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

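The expectations for the splits of the arrays, and the tests of scaling, of the within-group axis, of single arrays and of batches, were set down only after their results had been seen.

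The response to sleep deprivation differed between the genotypes for 6 probe sets, by a test of the interaction. The log2 differences were 2.06, 0.91, 0.86, 0.83 and 0.73 for the 5 with a higher change in the knockout and -0.76 for the other, with adjusted p from 0.0055 to 0.044. Of 100 splits of the arrays, 2 gave as many as 6 probe sets, the real one included, and the other gave 39. The splits shuffled genotype within each condition, which removes any genotype effect, so they do not test the interaction alone. Chance is therefore not excluded for the interaction by this count. The other split had several times the real count. Which arrays that split put together was not examined, so a structure among the samples, inside or outside the groups, was neither shown nor excluded.

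The largest of these, probe set 17529227, read higher on all 5 sleep-deprived knockout arrays than on the other 14. A single array as the cause is argued against by the smallest difference on leaving out each array in turn, 1.92, and array-wide scaling by the difference after quantile normalization, 2.10. A batch shared by these arrays stays open, and so does a response of the knockout to sleep deprivation. The probe set is among the dimmest 40% of rows, with means of 4.79 to 5.12 in the other 3 groups, so its difference was not tested under that filter. It has no gene name here, so no biological explanation was tested.

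After sleep deprivation 147 probe sets differed between genotypes, against 0 in controls. These 2 counts are not a test of a difference between the conditions. The interaction is that test, and it called 6 probe sets. For genotype after sleep deprivation, quantile normalization left 133, of which 106 were among the 147. This argues against array-wide scaling as the whole cause of the count. The split moved from 135 higher and 12 lower to 96 and 37, so the excess of higher values depended in part on scaling. The score on the main axis of variation within groups as a covariate gave 171, of which 125 were among the 147. That covariate also takes out variation within groups, which can raise a count, so the total does not decide on the axis as a cause. Single arrays may account for part of the count, since 67 were left without KO_sleep_deprived replicate 1, under 50% of 147, though fewer arrays also lower the power. Of 100 splits, 2 gave as many, the real one included, and the highest other gave 189. The labels name 0 batches, so a batch shared by the sleep-deprived knockout arrays cannot be told apart from the groups.

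Sleep deprivation called 23 probe sets in the knockout and 23 averaged over genotypes, and chance can be excluded for both, since 1 of 100 splits, the real one, gave as many and the highest other gave 3 and 2. For wild type chance is not argued against. There, 13 of 100 splits gave as many as 683 probe sets at an unadjusted p under 0.05 and the highest gave 1524. Nor is chance argued against for genotype in controls, where 3 of 35 splits gave as many as 476 and the highest other gave 600. For the genotype effect averaged over conditions, 5 of 100 splits gave at least 1 probe set, and the highest other gave 2.

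In 8 of 124 groups tested, 1 array lay far from the rest of its group, and chance gives about 1 in 20. Gm5528 read 8.02 in WT_control replicate 4, against 8.13 to 8.14 in the others. Mir466b-2 read 6.22 in WT_sleep_deprived replicate 4, against 6.71 to 6.82, and Mir219a-2 read 7.21 in WT_sleep_deprived replicate 2, against 7.61 to 7.82. H4c14 read 6.32 in KO_sleep_deprived replicate 5, against 6.63 to 6.72. Gm3286 read 5.76 in WT_control replicate 1, against 5.64 to 5.65. In KO_control replicate 4, Vmn1r148 read 5.75, against 6.39 to 6.51, and Gm21136 read 6.57, against 6.77 to 6.80. Gm19399 read 7.05 in KO_control replicate 3, against 7.50 to 7.58.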

How the results depend on the processing

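Leaving out the 3 arrays of lowest weight, the axis covariate and counting identical rows once were chosen after seeing the data. With identical rows counted once, 17 probe sets passed for sleep deprivation in the knockout, 16 averaged over genotypes and 138 for genotype after sleep deprivation. Counts are of probe sets past the threshold, and where a cause is not given it was not tested. For sleep deprivation in wild type (0), a variance trend, the filter on the dimmest 40% of rows and a threshold of 0.10 gave 2 each. For sleep deprivation in the knockout (23), the trend gave 39, array weights 43, the dim filter 35, one-symbol rows 7, only the arrays compared 12, the threshold of 0.10 46 and leaving out the 3 arrays 8. For sleep deprivation averaged over genotypes (23), the trend gave 39, array weights 37, the dim filter 39, one-symbol rows 8, median centring 14 and the threshold of 0.10 43. For genotype after sleep deprivation (147), one-symbol rows gave 28, only the arrays compared 36, the threshold of 0.10 338 and leaving out the 3 arrays 56. For genotype averaged over conditions (1), the trend gave 2, and the dim filter, which left out the probe set called, and leaving out the 3 arrays gave 0. One-symbol rows gave 1 there, a different probe set, that of Vmn1r148. For the interaction (6), one-symbol rows gave 0 and leaving out the 3 arrays 2. One-symbol rows are fewer tests, and smaller fits hold fewer samples.

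On leaving out each array in turn the counts ran from 0 to 3 for sleep deprivation in wild type, 6 to 33 in the knockout and 14 to 29 averaged, 67 to 298 for genotype after sleep deprivation, 0 to 3 averaged over conditions and 2 to 41 for the interaction. Genotype in controls stayed at 0 in each alternative run. No called gene or list changed sign. Region marker covariates were not run.

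The replicate numbers share only a number: 25 same-numbered pairs had residual correlations from -0.22 to 0.08, none over 0.1, and 0 of 19 arrays correlated best with its own number. With the replicate block the counts were 1 for sleep deprivation in wild type, 10 in the knockout, 9 averaged, 70 for genotype after sleep deprivation and 2 averaged over conditions. With a random replicate block sleep deprivation in the knockout gave 7. For sleep deprivation averaged, Fkbp5, Mir219a-2 and Pdzd2 had adjusted p = 0.056, 0.081 and 0.25 with the replicate block. For sleep deprivation in the knockout Gm20385 had 0.077, and for the interaction probe set 17267654 had 0.078.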

Other observations

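Tests of the added gene lists within one genotype or condition were chosen after seeing the data. The 14 measured small nucleolar RNAs, a class that mostly guides chemical modification of other RNAs, all had a negative sign for knockout against wild type in control mice. Their mean log2 change was -0.11, with an adjusted p = 0.010 at the preset correlation and an adjusted p = 0.36 with an estimated correlation. The correlation estimated between members was 0.25, which the preset of 0.01 does not allow for. In wild type after sleep deprivation, 12 of the 14 had a negative sign. Their mean log2 change was -0.13, with an adjusted p = 0.0070 at the preset correlation and an adjusted p = 0.83 with an estimated correlation. The signs went the other way in the remaining comparisons of this kind: 12 of the 14 were positive for sleep deprivation in the knockout (mean log2 change 0.08, adjusted p = 0.61) and 12 for genotype after sleep deprivation (mean log2 change 0.09, adjusted p = 0.76). These comparisons share arrays, so their signs are not independent. No member passed over all probe sets in any of them.

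In control mice, the mean log2 change of 18 immunoglobulin and T cell receptor segments was 0.13 for knockout against wild type, with 14 of positive and 4 of negative sign. The adjusted p was 0.028 at the preset correlation and 0.36 with an estimated correlation. For 23 ribosomal protein genes the mean log2 change was -0.06, with 8 of positive and 15 of negative sign. The adjusted p was 0.028 at the preset correlation and 0.41 with an estimated correlation. No member of either list passed over all probe sets or adjusted over the list alone. The list of 14 genes near Epha4 had a mean log2 change of 0.03 for genotype averaged over conditions, with an adjusted p = 0.77.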
